A study of Homo sapiens with 24 samples.

How the data were processed

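RNA was measured on 24 Affymetrix arrays as biotin-labelled cRNA, per the labels. The groups were DMSO and AZD3965 for 24 hours in HS578T, SUM149PT and SUM159PT, and scramble and MCT1 shRNA in SUM149PT, with 3 arrays each. The deposited intensity values are linear MAS5 signals, per the submitters' processing notes, and the software version is not given in the sources used here. Their trimmed mean, leaving out 2% of probe sets at each end, was 500.1 on every array, so the arrays had been scaled to a common level before deposition. No further normalization between arrays was applied, and every column of the table was assigned to a group by its label.

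The table held 54675 probe sets. In the annotation used here 41097 had 1 gene symbol, 1801 had several and 11777 had none, and 41043 of the symbols were looked up by gene ID in a reference table used for names only. The probe sets of the gene targeted by the shRNA were not named in that annotation, so its level and the labels of the knockdown were not checked here, and it is not reported. For each of 19775 genes the probe set with the highest mean over the 24 arrays was kept. The log2 of the value plus an offset of 16 was analysed, which damps noise near 0 and understates fold changes of dim genes. Genes whose mean log2 value was at or above the 40th percentile of all probe sets (5.58) were tested, 14141 in all. The probe sets without a single symbol were tested separately.

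One linear model with 8 group means was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (16 residual degrees of freedom, 6.52 prior degrees of freedom, eBayes with a mean-variance trend). Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Contrasts were MCT1 shRNA minus scramble, AZD3965 minus DMSO in each line and averaged over lines, an F test of whether the AZD3965 effect differed between lines, the shRNA effect minus the AZD3965 effect in SUM149PT, and an F test between lines under DMSO. Pairwise differences were given beside both F tests. Errors of log2 fold changes are standard errors and those of signals are standard deviations.

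Lists of genes written from general knowledge before the data were examined, 34 with at least 3 measured members, were tested with camera in limma at a preset correlation between genes of 0.01. The tests were repeated with the correlation estimated, and p-values were adjusted over the lists within a contrast. They covered the lists named in the report of the shRNA comparison. Of 705 planned list entries, 65 were not named in the annotation used and 599 were measured after the filter, so counts and medians rest on part of most lists. The monocarboxylate transporter list kept 4 of 8 entries. Members past the threshold were counted both adjusted over all genes and adjusted over the list alone. For reference, list medians were set against those of 10000 random lists matched on mean expression in 50 bins.

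Genes were named by a rule fixed before the data were examined. In every comparison it took SLC16A7 and BSG. The rule as planned also held the targeted gene and another transporter gene, which are not reported here. It further took the genes of largest rise and largest fall among those called whose treated and control arrays did not overlap. These were 8 each way for the shRNA effect and the average, and 4 each way elsewhere. It also took up to 4 members of smallest p in each called list, LDHA, TXNIP, HK2 and PDK1 for the shRNA effect and the average, the 4 genes highest in each line with 5 markers, and the 3 of smallest p each way where no gene passed. For the average the same sign in all lines replaced the overlap condition. The rule had not foreseen differences of effects. For the shRNA effect against the AZD3965 effect, deviations of treated arrays from their own control mean had to be without overlap. For differences between lines, HS578T deviations had not to overlap those of the other lines, and genes were ranked by the HS578T effect minus the mean of the others.

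The pipeline was tested on simulated data in which 200 of 14141 genes were changed in each comparison. Of genes changed 1.5-fold, 57% were recovered for the shRNA contrast, 46% for HS578T, 51% for SUM149PT and 48% for SUM159PT, and of those changed 2-fold 77%, 78%, 79% and 73%. False calls made up 4.29%, 6.77%, 7.14% and 2.42% of calls. A shifted list was called at adjusted p = 8.60e-21 and 0 of 33 other lists were called by camera. Errors were simulated independently for each gene, so this cannot show how often correlation between genes gives false list calls. They were also normal with the same spread on all arrays, whereas the residual SD of the real arrays ran from 0.180 to 0.296. Folds were added after the offset, which a dim gene reaches only with a larger fold in signal. Recovery and false calls may therefore be less favourable in the real data.

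Alternatives were quantile normalization, median centring, other offsets and filters, the mean of a gene's probe sets, no trend, array weights, only the arrays of a comparison, a replicate block, an estimated correlation, and leaving out each array in turn. Leaving out scramble shRNA array 3 as a remedy for its control ratios, the random lists, and median centring, the 60th percentile filter, offset 64 and array weights for the gene lists were added after the data were seen. The array was kept in the results reported first.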

Results

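Gene expression was measured on 24 Affymetrix arrays from 3 established human breast cancer cell lines, HS578T, SUM149PT and SUM159PT, in 8 groups of 3 arrays. In the inhibitor experiment, 18 arrays compared cells given AZD3965, an inhibitor of the lactate and pyruvate transporter MCT1, for 24 hours with cells given DMSO, in each of the 3 lines. In the shRNA experiment, 6 arrays compared SUM149PT cells carrying a lentiviral shRNA against MCT1 with cells carrying a scrambled shRNA, both selected for 5 days with puromycin at 2 µg/ml. According to the study's design text the lines are highly glycolytic, and the question was whether MCT1 contributes to that metabolic state.

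The deposited signals ran from 0.0284 to 52949 units. The median signal of an array lay between 49.2 and 67.4 and the 99th percentile between 12490 and 15258. Each array correlated with the others of its group at a mean r of 0.969 to 0.989 across probe sets, which are not independent replicates. With 3 arrays per group, their number limits the precision of every value. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. On scramble shRNA array 3 the actin control probe sets had a 3' to 5' signal ratio of 53.8, against 1.2 to 2.14 on the other arrays. Its GAPDH ratio was 2.35, against 0.798 to 0.948, and its mean r to its group was the lowest at 0.969. The actin ratio of 2.14 was that of scramble shRNA array 1. Every shRNA array had a higher actin ratio than any inhibitor array. The lowest shRNA value was 1.39 (MCT1 shRNA array 1), and the highest inhibitor value 1.37 (SUM159PT AZD3965 array 2). GAPDH ratios of the other shRNA arrays lay within the range of the inhibitor arrays. The cause of the actin difference between the experiments was not tested.

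**Figure D1:**
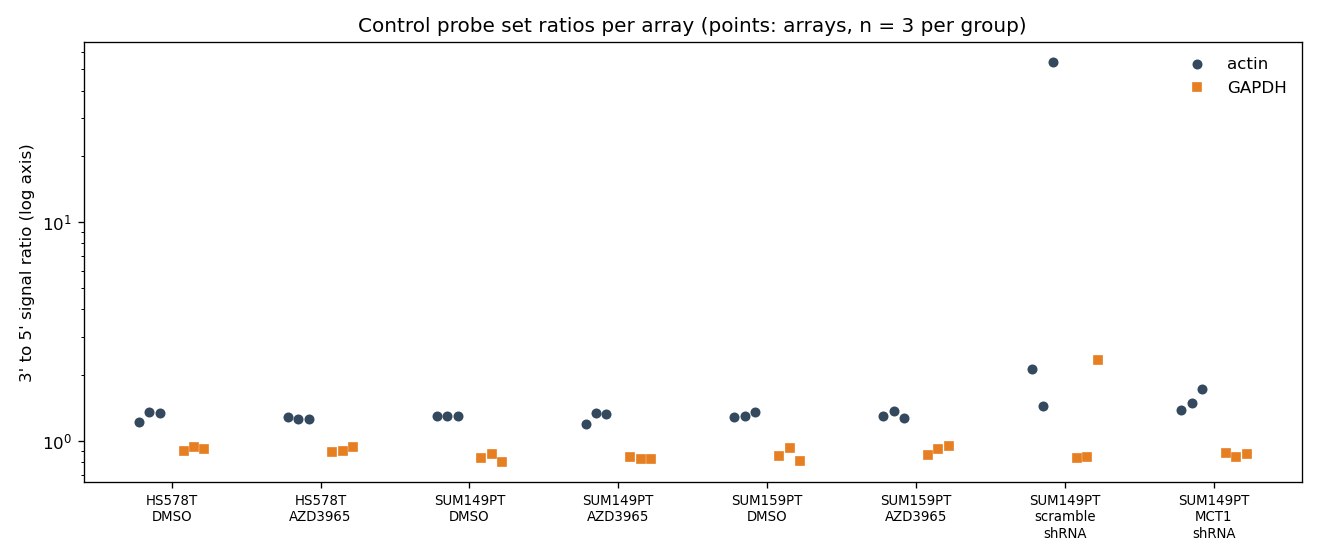
Ratio of the 3' to the 5' control probe set signal (log axis, no unit) for actin and GAPDH on each of the 24 arrays, by group; each point is 1 array. Scramble shRNA array 3 lies at 53.8 for actin and 2.35 for GAPDH, and the other arrays reach at most 2.14 and 0.948.

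The shRNA comparison asked how SUM149PT expression differed when MCT1 rather than a scrambled sequence was targeted. The largest rise was in AGR2, a protein disulfide isomerase of the secretory pathway, from 276 ± 22.5 to 3802 ± 192 signal units (SD, n = 3 per group), a log2 fold change of 3.71 ± 0.16 (SE; limma adjusted p = 2.83e-13). The transcription factor gene KLF4 rose from 383 ± 82.2 to 2070 ± 111 units, by 2.41 ± 0.10 on the log2 scale. MGP, a matrix protein gene, rose by 2.45 ± 0.19, CH25H, an oxysterol-forming hydroxylase, by 2.45 ± 0.25, and ECM2, another matrix gene, by 2.39 ± 0.20. INHBE, an activin subunit gene, rose by 2.19 ± 0.27, PPARGC1A, a coactivator of mitochondrial biogenesis, by 2.11 ± 0.31, and CHAC1, a glutathione-degrading enzyme, by 2.03 ± 0.17. IGFBP7, a secreted insulin-like growth factor binding protein, fell from 177 ± 65.7 to 9.56 ± 1.74 units, a log2 change of -2.85 ± 0.16. Its signal with MCT1 shRNA lay under the offset of 16, which largely sets that size: the change was -4.01 with an offset of 1 and -1.67 with an offset of 64. The histone gene H3C8 changed by -1.91 ± 0.49, ANKRD34A by -1.65 ± 0.23, the actin-binding gene TAGLN by -1.60 ± 0.16 and CCBE1, a lymphatic growth factor cofactor, by -1.60 ± 0.16. The ANKRD34A signal of 11.9 units with MCT1 shRNA was also under the offset, and its change was -2.50 with an offset of 1 and -0.84 with an offset of 64. The kinase gene LCK changed by -1.44 ± 0.30, the collagen gene COL15A1 by -1.35 ± 0.20 and the synaptic adhesion gene NLGN1 by -1.35 ± 0.17. In each of these 16 genes all 3 MCT1 shRNA arrays lay beyond all 3 scramble arrays, with adjusted p between 2.83e-13 and 0.00946. Passing the threshold and not overlapping were conditions for naming these genes, so neither adds separate support. The H3C8 call was lost without MCT1 shRNA array 1 (adjusted p = 0.0746).

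Of 14141 genes tested, 2101 differed, 1021 higher and 1080 lower with MCT1 shRNA. Changes of at least 1.5-fold numbered 719, and 161 reached 2-fold. With only the 6 shRNA arrays fitted the count was 864. In 1998 of the called genes the 3 arrays of one group lay beyond all 3 of the other. Chance gives that ordering in 10% of unselected genes, which is no benchmark for genes called between the same arrays. The share of called genes that were higher was 48.6%, and 34.4% when each array was centred on its median, so the balance of directions depended on the scaling. Without scramble shRNA array 3, which was singled out after its ratios were seen, 1735 genes passed (870 higher, 865 lower). Of the 2101 genes, 1409 (67.1%) passed in the same direction without that array, against 1462, 1470 and 1479 without single MCT1 shRNA arrays and 1637 and 1782 without the other scramble arrays.

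Genes on the list for ATF4 and the amino acid stress response rose together, though what triggered the rise was not tested. Of 28 measured genes on the list for ATF4, a transcription factor induced by amino acid shortage, 22 rose and 6 did not pass (24 rose adjusted over the list alone), with a median log2 fold change of 0.63. The camera adjusted p was 3.55e-26, and 2.01e-06 with an estimated correlation. Besides CHAC1, NUPR1 rose by 1.90 ± 0.15, and SLC3A2 and SLC7A11, which form the cystine transporter, by 1.59 ± 0.08 and 1.38 ± 0.10. Of 19 genes of the endoplasmic reticulum unfolded protein response, 10 rose, 2 fell and 7 did not pass, with the same counts adjusted over the list alone and a median of 0.35. The adjusted p was 3.04e-07, and 0.0037 with an estimated correlation. Examples were the chaperone gene DNAJB9 (1.57 ± 0.07), the degradation factor HERPUD1 (1.12 ± 0.07), the transcription factor XBP1 (0.70 ± 0.10) and EDEM1 (0.65 ± 0.09). Among 13 genes of glutamine and aspartate metabolism, 5 rose and 8 did not pass (6 rose adjusted over the list alone). The median was 0.02 and the mean 0.31 (adjusted p = 7.46e-04, and 0.0140 with an estimated correlation), so the members were uneven. Asparagine synthetase ASNS rose by 1.25 ± 0.07, ASS1, an enzyme of arginine synthesis, by 1.23 ± 0.08, and the transporters SLC1A5 and SLC38A1 by 0.91 ± 0.12 and 0.40 ± 0.08. Of 11 genes of serine, glycine and one-carbon metabolism, 5 rose and 1 fell (5 and 2 adjusted over the list alone), with a median of 0.24. That list passed at adjusted p = 0.0067 but not with an estimated correlation (adjusted p = 0.0608 with an estimated correlation). Its examples were ALDH1L2 (1.70 ± 0.20), the transporter SLC1A4 (1.16 ± 0.14), PHGDH (0.76 ± 0.12) and PSAT1 (0.45 ± 0.08). Without the array of high 3' to 5' ratio these 4 lists had adjusted p of 1.64e-27, 1.36e-06, 0.00133 and 0.0101 in the order given.

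**Figure D2:**
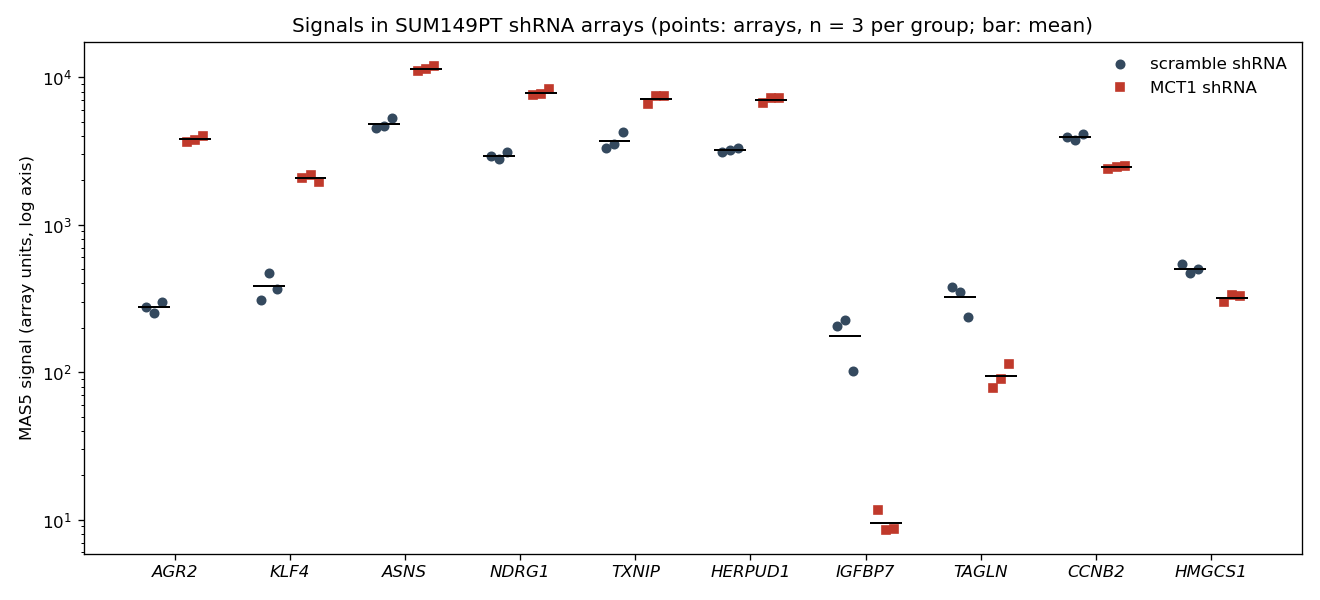
Array signal (MAS5 units, log axis) of 10 genes on the 6 SUM149PT shRNA arrays; points are single arrays, bars are means of 3. AGR2 (means 276 and 3802), KLF4, ASNS, NDRG1, TXNIP and HERPUD1 lie higher with MCT1 shRNA on all 3 arrays, and IGFBP7 (means 177 and 9.56), TAGLN, CCNB2 and HMGCS1 lie lower; CCNB2 did not pass when its probe sets were averaged (adjusted p = 0.543).

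Hypoxia-responsive genes were also higher. Of 23 measured, 12 rose and 11 did not pass (13 rose adjusted over the list alone), with a median of 0.29 (camera adjusted p = 1.48e-08, and 5.73e-05 with an estimated correlation). NDRG1, a stress-induced gene, rose by 1.41 ± 0.08, the angiogenic factor VEGFA by 1.07 ± 0.11, the vasodilator peptide gene ADM by 0.81 ± 0.10 and the collagen prolyl hydroxylase gene P4HA1 by 0.62 ± 0.06. Of 6 genes tied to MondoA, a glucose-sensing transcription factor, 4 rose (5 adjusted over the list alone), with a median of 0.47 (adjusted p = 5.76e-04, and 0.00788 with an estimated correlation). TXNIP, which restrains glucose uptake, rose from 3685 ± 488 to 7154 ± 524 units (0.96 ± 0.10). ARRDC3 rose by 0.96 ± 0.18, ARRDC4 by 0.48 ± 0.12 and KLF10 by 0.46 ± 0.09. Of 17 fatty acid oxidation genes, 4 rose and 13 did not pass, also adjusted over the list alone, with a median of 0.15 (adjusted p = 0.0190, and 0.0427 with an estimated correlation). CPT1A, which admits fatty acids to mitochondria, rose by 0.54 ± 0.14, ECI1 by 0.44 ± 0.14, ETFDH by 0.43 ± 0.10 and HADHA by 0.42 ± 0.10. Without scramble shRNA array 3 the 3 lists had adjusted p of 1.31e-08, 0.00118 and 0.0133. CPT1A, ECI1 and HADHA then measured only 0.28, 0.33 and 0.26 and did not pass (limma adjusted p = 0.0542, 0.147 and 0.0574). HADHA was also lost without MCT1 shRNA array 1 (0.0588), ARRDC4 without MCT1 shRNA array 3 (0.0508), and ECI1 without MCT1 shRNA arrays 1 and 2 or scramble array 2 (0.0868, 0.0978 and 0.0544). With the mean of a gene's probe sets, the oxidation list (adjusted p = 0.0729), HADHA (0.0992) and P4HA1 (0.267) did not pass.

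Cell division genes fell. Of 28 mitotic genes, 23 fell and 5 did not pass (25 fell adjusted over the list alone), with a median of -0.41 (camera adjusted p = 8.31e-21, and 1.05e-06 with an estimated correlation). The kinesin gene KIF20A changed by -0.71 ± 0.07, the cyclin gene CCNB2 by -0.67 ± 0.06, the spindle gene DLGAP5 by -0.57 ± 0.06 and the checkpoint kinase gene BUB1 by -0.56 ± 0.06. Of 26 DNA replication genes, 10 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -0.24 (adjusted p = 2.73e-04, and 0.0232 with an estimated correlation). POLE2 changed by -0.52 ± 0.08, the helicase subunits MCM5 and MCM3 by -0.47 ± 0.12 and -0.39 ± 0.07, and RFC3 by -0.28 ± 0.06. Of 19 genes of cholesterol synthesis and uptake, 7 fell and 12 did not pass (11 fell adjusted over the list alone), with a median of -0.24 (adjusted p = 7.46e-04, and 0.0232 with an estimated correlation). HMGCS1, an early enzyme of the pathway, changed by -0.63 ± 0.11, ACAT2 by -0.42 ± 0.08, the feedback regulator INSIG1 by -0.39 ± 0.10 and FDPS by -0.30 ± 0.07. Of 21 epithelial and luminal markers, 4 rose (5 adjusted over the list alone), with a median of 0.20 (adjusted p = 3.64e-04). This call was lost in the other version of the test (adjusted p = 0.0608 with an estimated correlation). Besides AGR2, the keratin genes KRT19 and KRT8 rose by 1.09 ± 0.10 and 0.64 ± 0.17 and GATA3, a luminal transcription factor, by 0.60 ± 0.12. Without scramble shRNA array 3 these 4 lists had adjusted p of 2.69e-23, 2.08e-05, 0.00118 and 7.32e-04. KRT8 (0.33, limma adjusted p = 0.0798) and MCM5 (-0.32, 0.0593) then did not pass. MCM5 was also lost without MCT1 shRNA array 2 (0.0524). With the mean of a gene's probe sets BUB1 turned to 0.12 (adjusted p = 0.632), and CCNB2 (-0.17, 0.543) and RFC3 (-0.11, 0.570) did not pass.

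Of the genes nearest to the target, the related transporter gene SLC16A7 rose from 444 ± 172 to 774 ± 107 units (0.84 ± 0.24, adjusted p = 0.0205), while BSG, which encodes a chaperone of these transporters, measured 0.04 ± 0.07 (0.805). The SLC16A7 call was lost without scramble arrays 1 or 3 (adjusted p = 0.0762 and 0.111) and without MCT1 shRNA arrays 1 or 2 (0.0607 and 0.0847). The hexokinase gene HK2 rose by 0.42 ± 0.14 (0.0447) and passed in 1 of 6 fits that left out an array, where adjusted p reached 0.132 without scramble array 3, and it measured 0.09 (0.628) with the mean of its probe sets. The lactate dehydrogenase gene LDHA measured 0.14 ± 0.12 (0.487) and the pyruvate dehydrogenase kinase gene PDK1 0.27 ± 0.10 (0.0661), neither of which passed. The glycolysis list, with 3 of 21 genes higher, did not pass (median 0.05, camera adjusted p = 0.252), nor did monocarboxylate transporters (0.309), pyruvate entry and TCA cycle (0.312), oxidative phosphorylation (0.922) or the pentose phosphate pathway (0.922). Without scramble shRNA array 3, oxidative phosphorylation passed with the opposite sign (median 0.10 against -0.02, adjusted p = 0.00368), and the autophagy and lysosome list passed at 0.00622 (0.0536 with all arrays). The leukocyte, endothelial and adipocyte marker lists did not pass (0.961, 0.932 and 0.371), nor did basal (0.479) and mesenchymal markers (0.961) or stable reference genes (0.922). The adjusted p was 0.301 for fatty acid synthesis, 0.275 for heat shock, 0.804 for NRF2, 0.309 for pH regulation, 0.922 for p53, 0.922 for type I interferon and 0.312 for NF-kappaB. It was 0.932 for immediate early genes, 0.922 for YAP and TAZ targets, 0.922 for nucleolar genes and 0.954 for mitochondrial biogenesis regulators. The median, mean and test differed in sign for the pentose phosphate, p53, immediate early, mitochondrial biogenesis, leukocyte and endothelial lists. With the 6 shRNA arrays fitted alone, CPT1A, ECI1, ETFDH, HADHA, FDPS, KLF10, KRT8, MCM5, RFC3 and SLC16A7 did not pass (adjusted p from 0.0605 to 0.154).

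In HS578T, 24 hours of AZD3965 raised hypoxia-responsive and glycolytic genes. PDK1, a kinase that limits pyruvate entry into the mitochondrial cycle, rose from 818 ± 84.3 to 1557 ± 123 units (SD, n = 3 per group), a log2 fold change of 0.92 ± 0.10 (SE; limma adjusted p = 1.52e-05). Of 23 hypoxia-responsive genes, 6 rose and 17 did not pass, while 17 rose adjusted over the list alone, with a median of 0.32 (camera adjusted p = 9.23e-33, and 1.22e-08 with an estimated correlation). The adenylate kinase gene AK4 rose by 0.81 ± 0.10, the mitophagy receptor gene BNIP3 by 0.65 ± 0.06, the repressor gene BHLHE40 by 0.62 ± 0.09 and P4HA1 by 0.49 ± 0.06. Of 21 glycolysis genes, 2 rose over all genes tested and 10 adjusted over the list alone, with a median of 0.24 (adjusted p = 6.87e-14, and 0.0141 with an estimated correlation). The enolase gene ENO2 rose by 0.71 ± 0.15 and the glucose transporter gene SLC2A1 by 0.44 ± 0.07, while HK2 at 0.62 ± 0.14 (0.0649) and PGK1 at 0.28 ± 0.07 (0.142) did not pass. The neuronal adhesion genes NRXN3 and TENM2 rose by 0.91 ± 0.19 and 0.86 ± 0.16 and PNLIPRP3 by 0.90 ± 0.18. The homeobox gene DLX3 changed by -1.33 ± 0.25, the cytokine gene TNF by -1.04 ± 0.20, WNT10A by -1.03 ± 0.21 and LOC389906 by -0.96 ± 0.15. DLX3, TNF, WNT10A and PNLIPRP3 had group means under 60 units, where the offset largely sets the size of the change. With an offset of 64 TNF (-0.48, adjusted p = 0.0928), WNT10A (-0.41, 0.311) and PNLIPRP3 (0.33, 0.338) did not pass, while DLX3 did (-0.64, 0.0476).

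Unfolded protein response genes were higher in HS578T: 1 of 19, the secreted neurotrophic factor gene MANF (0.36 ± 0.07, adjusted p = 0.0124), rose over all genes and 5 adjusted over the list alone. Their median was 0.11 (camera adjusted p = 8.56e-08, and 0.00317 with an estimated correlation), and HSPA5 measured 0.36 ± 0.10 (0.205), SDF2L1 0.35 ± 0.10 (0.164) and HERPUD1 0.28 ± 0.07 (0.107). Cholesterol synthesis and uptake had a median of 0.14 over 19 genes (adjusted p = 9.77e-06, and 0.00581 with an estimated correlation), with 1 gene passing adjusted over the list alone; FDPS measured 0.31 ± 0.07 (0.0519), HMGCS1 0.26 ± 0.11 and DHCR7 0.24 ± 0.09. Fatty acid synthesis had a median of 0.13 over 12 genes (0.00498, and 0.0335 with an estimated correlation), 1 passing adjusted over the list alone, with ELOVL6 at 0.51 ± 0.13 (0.126), FADS2 at 0.50 ± 0.21 and ACSS2 at 0.21 ± 0.11. YAP and TAZ targets had a median of 0.14 over 20 genes (2.85e-04, and 0.0141 with an estimated correlation), 2 passing adjusted over the list alone, with the coagulation factor gene F3 at 0.43 ± 0.13 (0.234), GADD45B at 0.27 ± 0.09 and TGFB2 at 0.24 ± 0.10. Mitotic genes had a median of -0.11, with 25 of 28 lower (2.86e-05, and 0.00317 with an estimated correlation), but no single gene passed by limma even adjusted over the list alone; PLK1 measured -0.31 ± 0.12 (0.449), CDCA8 -0.20 ± 0.08, KIF20A -0.17 ± 0.07 and AURKA -0.14 ± 0.06. Pyruvate entry and the TCA cycle passed at 0.0140 with a median of 0.03 over 28 genes, of which PDK1 alone passed, also adjusted over the list alone; IDH2 measured 0.25 ± 0.09 and SUCLG2 0.21 ± 0.09. The pentose phosphate list passed at 0.0140 with a median of 0.07 and 9 of 9 genes higher, with ME1 at 0.18 ± 0.06 (0.344), RPE at 0.19 ± 0.09 and IDH1 at 0.16 ± 0.11. Both calls were lost in the other version of the test, at adjusted p = 0.0713 and adjusted p = 0.115 with an estimated correlation. SLC16A7 measured -0.34 ± 0.24 (0.787) and BSG 0.05 ± 0.07 (0.945). The other 25 lists did not pass, the MondoA list coming nearest (0.0842), and the leukocyte, endothelial and adipocyte lists lay at 0.961, 0.574 and 0.918. Of the 9 lists called in HS578T, 7 stayed called in the same direction under quantile normalization, and 7 with the mean of probe sets. The median signal was 50.2 to 53.5 on the HS578T AZD3965 arrays and 59.4 to 60.5 on the HS578T DMSO arrays, without overlap. Only the hypoxia list was weighed against scaling by intensity in this line, so such scaling was not excluded for its other lists.

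In all, 43 genes differed in HS578T, 30 higher and 13 lower, 23 of them by at least 1.5-fold and 3 by at least 2-fold. All 43 had non-overlapping arrays, which chance gives in 10% of unselected genes and which is no separate test of genes called between the same arrays. An unadjusted p under 0.05 was found for 1171 genes (8.28%), where chance alone gives a share of 0.05. With array weights the count was 388, including all 43, with the mean of probe sets 26 and with only the 6 arrays fitted 28. The share that were higher was 69.8%, and 84.6% with each array centred on its median. The count was 24 without DMSO array 1, 23 without DMSO array 3, 15 without AZD3965 array 1 and 27 without AZD3965 array 3. PDK1, AK4, BNIP3, BHLHE40, P4HA1 and LOC389906 passed in all 6 fits that left out an array. SLC2A1 was lost without DMSO array 3 (adjusted p = 0.0538) and MANF without DMSO array 2 or AZD3965 array 3 (0.0890 and 0.118). NRXN3 was lost in all 6 fits, ENO2 and PNLIPRP3 in 5, TENM2 and WNT10A in 4, and DLX3 and TNF in 3, with adjusted p up to 0.179 for NRXN3 without AZD3965 array 3. The pyruvate and TCA list was lost without DMSO array 3 (0.0557) or AZD3965 array 1 (0.0592). With the mean of a gene's probe sets PDK1 measured 0.40 (0.142), P4HA1 0.10 (0.964), BHLHE40 0.58 (0.0626), SLC2A1 0.44 (0.0792) and LOC389906 -0.36 (0.281), none of which passed.

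**Figure D3:**
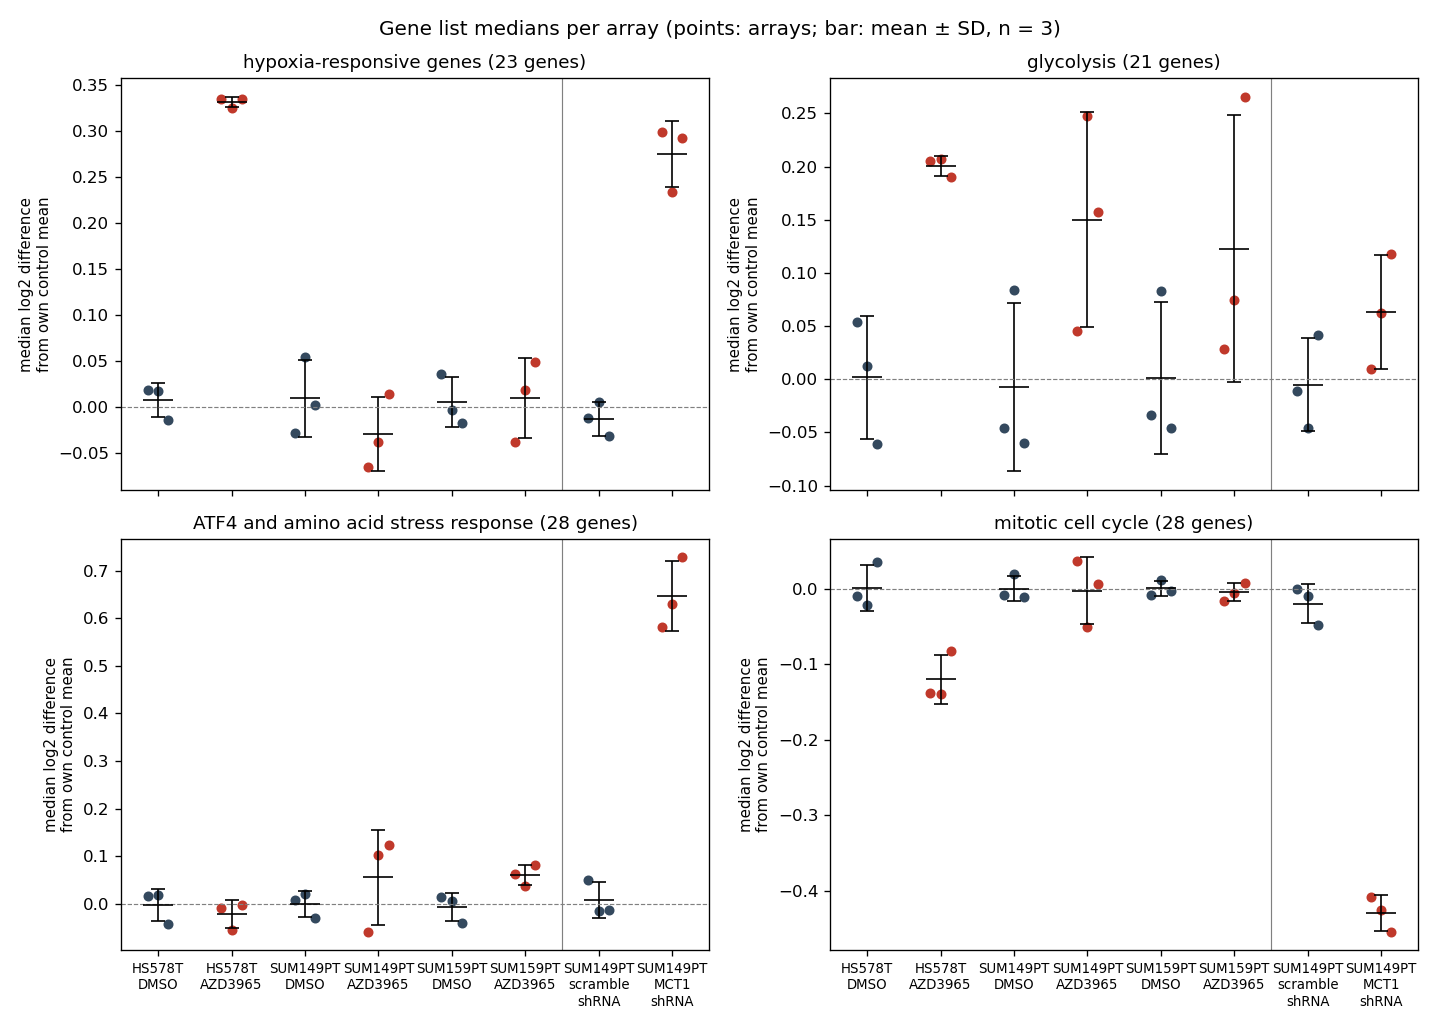
Median log2 difference of a list's genes from the mean of the control arrays of the same cell line and experiment, per array, for hypoxia-responsive (23 genes), glycolysis (21), ATF4 (28) and mitotic (28) lists; points are arrays and bars are mean ± SD of 3. Hypoxia-responsive genes lie higher in HS578T with AZD3965 (list median 0.32) and in SUM149PT with MCT1 shRNA (0.29), and the ATF4 list lies higher (0.63) and the mitotic list lower (-0.41) with MCT1 shRNA.

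In SUM149PT, AZD3965 changed 4 genes. CCDC127, a gene of little-known function, rose from 891 ± 109 to 1772 ± 272 units (log2 fold change 0.97 ± 0.11, SE, n = 3 per group, limma adjusted p = 2.15e-04). CYB561D1, a cytochrome b561 family gene, rose by 0.83 ± 0.12 (0.00335) and DANCR, a long noncoding RNA, by 0.57 ± 0.10 (0.0200). The glutamate receptor gene GRIK2 changed by -1.47 ± 0.22 (0.00335), from 64.1 ± 25.2 to 12.2 ± 2.22 units. The lower signal was under the offset of 16, and the GRIK2 change was -2.25 with an offset of 1 and -0.73 with an offset of 64, where it did not pass (0.0856). In all 4 the arrays of the groups did not overlap, which is no separate test of genes called between the same arrays. SLC16A7 measured -0.33 ± 0.24 (0.514) and BSG 0.20 ± 0.07 (0.191). Oxidative phosphorylation genes had a median of 0.14, with 43 of 48 higher (camera adjusted p = 1.15e-04), and glycolysis genes 0.17 (0.0485), with 2 of 21 higher and 1 lower adjusted over the list alone. Stable reference genes had a median of 0.16, with 10 of 11 higher (0.0329). YAP and TAZ targets had a median of -0.22 (0.00919), with 3 of 20 lower adjusted over the list alone. These 4 calls were lost in the other version of the test, at adjusted p = 0.706, adjusted p = 0.706, adjusted p = 0.706 and adjusted p = 0.256 with an estimated correlation. No list member passed over all genes tested: ATP5F1B measured 0.31 ± 0.09 (0.143), NDUFV1 0.28 ± 0.10, ALDOA 0.32 ± 0.11 (0.165), LDHB 0.31 ± 0.10, PPIA 0.36 ± 0.12, ACTB 0.36 ± 0.13, MYOF -0.25 ± 0.06 (0.14) and ASAP1 -0.34 ± 0.10. Hypoxia-responsive genes, the nearest of the other 30 lists, did not pass (0.365).

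In SUM149PT 2330 genes (16.5%) had an unadjusted p under 0.05, where chance alone gives a share of 0.05. With array weights 188 genes passed, 38.3% of them higher against 75% of the 4, and with the mean of probe sets 2. Without AZD3965 array 1, 648 genes passed, 2 without DMSO array 1, 17 without DMSO array 2 and 7 without AZD3965 array 3. DANCR was lost without DMSO array 1 or AZD3965 arrays 2 or 3 (adjusted p = 0.194, 0.195 and 0.109) and GRIK2 without DMSO array 1 (0.0599). Lists called numbered 2 without DMSO array 3 or AZD3965 array 2 and 1 without AZD3965 array 3. With the 6 arrays fitted alone the 4 genes had an adjusted p of 0.237, and CCDC127 measured 0.25 (0.330) with the mean of its probe sets. Under quantile normalization the YAP and TAZ list passed, while oxidative phosphorylation (0.564) and glycolysis (0.966) did not and reference genes measured -0.03 (0.966). AZD3965 arrays 2 and 3 in SUM149PT and AZD3965 array 3 in SUM159PT had the highest maximum signals, 52949, 51309 and 50953, against at most 41443 on the other arrays. The 99th percentile was 1.08 times that of DMSO in SUM149PT and 1.06 times in SUM159PT (exact two-sided permutation p = 0.2 in both, the smallest possible being 0.1).

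In SUM159PT limma called 0 genes. There 954 genes (6.75%) had an unadjusted p under 0.05, near the share of 0.05 that chance alone gives. The lowest p-values, none past the threshold, were for the tumour suppressor gene WT1 (log2 fold change -1.02 ± 0.17, SE, n = 3 per group, adjusted p = 0.0516), NAPRT, an enzyme of NAD synthesis (-0.96 ± 0.17, 0.0516), the cyclooxygenase gene PTGS2 (0.93 ± 0.17, 0.0951), SLC35D2 (-0.54 ± 0.11, 0.102), LINC01315 (0.92 ± 0.19, 0.15) and the proteoglycan gene BGN (0.92 ± 0.21, 0.426). Most lay near the floor: PTGS2 measured 10.2 ± 6.53 and 33.3 ± 6.31 units and WT1 48.4 ± 6.26 and 16.9 ± 10.3. SLC16A7 measured -0.28 ± 0.24 (0.834) and BSG 0.13 ± 0.07 (0.741). Oxidative phosphorylation had a median of 0.10 with 41 of 48 genes higher (camera adjusted p = 3.28e-06), glycolysis 0.12 with 18 of 21 higher (0.00425), and reference genes 0.12 with 11 of 11 higher (0.00365). Leukocyte markers had a median of -0.53 with 5 of 6 genes lower (0.0140): CD14 measured -0.56 ± 0.28, CD2 -0.58 ± 0.29, CD79A -0.48 ± 0.28 and ITGAM -0.51 ± 0.23, at group means of 13.0 to 363 units. These calls were lost in the other version of the test, at adjusted p = 0.692, adjusted p = 0.565, adjusted p = 0.446 and adjusted p = 0.446 with an estimated correlation, and no member passed adjusted over the list alone by limma. Members with the smallest p were ATP5F1A (0.22 ± 0.09), LDHA (0.24 ± 0.12), ALDOA (0.23 ± 0.11) and PPIA (0.25 ± 0.12), each at adjusted p = 0.728.

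The SUM159PT gene count was 9 with an offset of 1, 5 with array weights, 2 with the filter at the 60th percentile and 1 under quantile normalization or median centring. It was 2 without DMSO array 1, 4 without DMSO array 3, 3 without AZD3965 array 1 and 2 without AZD3965 array 2. Lists called numbered 2 without DMSO array 3, 7 without AZD3965 array 1 and 1 without AZD3965 array 3; without that last array glycolysis (0.374), oxidative phosphorylation (0.0651) and reference genes (0.187) did not pass. Under quantile normalization 0 lists passed by camera in SUM159PT, oxidative phosphorylation at 0.240 and leukocyte markers at 0.0979.

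Averaged over the 3 lines, 4 genes rose with AZD3965 and had the same sign in every line. CCDC127 rose by 0.40 ± 0.07 (SE, limma adjusted p = 0.0237), RILPL1, a gene of ciliary transport, by 0.34 ± 0.06 (0.0465), IER3, a stress-response gene, by 0.29 ± 0.05 (0.0252) and BNIP3 by 0.24 ± 0.04 (0.0183). IER3 measured 0.33, 0.27 and 0.27 and RILPL1 0.39, 0.30 and 0.33 in HS578T, SUM149PT and SUM159PT, whereas BNIP3 measured 0.65, 0.00 and 0.06 and CCDC127 0.20, 0.97 and 0.02. PDK1 measured 0.24 ± 0.06 (0.13), LDHA 0.20 ± 0.07 (0.223), TXNIP 0.18 ± 0.06 (0.214), HK2 -0.06 ± 0.08 (0.770), SLC16A7 -0.32 ± 0.14 (0.299) and BSG 0.12 ± 0.04 (0.223). Hypoxia-responsive genes had a median of 0.11, with 1 of 23 higher over all genes and 10 adjusted over the list alone (camera adjusted p = 5.70e-07, and 6.04e-04 with an estimated correlation). Against the DMSO mean, the list median was 0.334, 0.325 and 0.334 on the HS578T AZD3965 arrays. It was -0.066, -0.038 and 0.014 in SUM149PT and -0.038, 0.018 and 0.048 in SUM159PT, so the rise lay in HS578T and was not shared by the lines. Members besides BNIP3 were FAM162A (0.35 ± 0.07, 0.0747), AK4 (0.22 ± 0.06) and BHLHE40 (0.21 ± 0.05). Glycolysis had a median of 0.16, with 14 of 21 higher adjusted over the list alone (5.85e-11), led by PGK1 (0.19 ± 0.04, 0.0945), PFKP (0.22 ± 0.05) and PFKL (0.23 ± 0.06). Oxidative phosphorylation had a median of 0.08 (1.03e-07), with COX4I1 at 0.15 ± 0.05, and reference genes 0.11 with 7 higher and 1 lower adjusted over the list alone (3.11e-04). The unfolded protein response had a median of 0.05 with 4 higher adjusted over the list alone (0.00248), and MANF measured 0.18 ± 0.04 (0.0779). Mitotic genes had a median of -0.05 with 6 lower adjusted over the list alone (0.00584), and KIF11 measured -0.19 ± 0.05 (0.187). These 5 calls were lost in the other version of the test, at adjusted p = 0.0517, adjusted p = 0.425, adjusted p = 0.254, adjusted p = 0.0978 and adjusted p = 0.0517 with an estimated correlation.

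For the average 2048 genes (14.5%) had an unadjusted p under 0.05, where chance alone gives a share of 0.05. The count was 147 with array weights (70.7% higher), 0 by limma without the trend, 9 with only the 18 arrays of the inhibitor experiment and 7 under median centring or with an offset of 1. The count of 4 was 0 without HS578T DMSO array 2 or AZD3965 array 1 or SUM149PT DMSO array 1 or AZD3965 array 3, and 1 without SUM159PT AZD3965 arrays 1 or 3. It was 2 without HS578T DMSO array 3, HS578T AZD3965 array 2, SUM149PT DMSO array 3, SUM149PT AZD3965 array 2 or SUM159PT DMSO arrays 1 or 3, and rose to 15 without HS578T DMSO array 1, 66 without SUM149PT AZD3965 array 1 and 11 without SUM159PT AZD3965 array 2. BNIP3 passed in 14 of the 18 fits that left out an array, CCDC127 in 9, and IER3 and RILPL1 in 5, with adjusted p up to 0.163.

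The effect of AZD3965 differed between lines for 17 genes. PDK1 had log2 fold changes of 0.92 ± 0.10 in HS578T, -0.21 ± 0.10 in SUM149PT and 0.02 ± 0.10 in SUM159PT (SE, n = 3 per group, adjusted p of the limma F test 7.41e-04). Errors are equal across the lines because each gene's spread was estimated over all groups. HK2, which traps glucose in the cell, had 0.62 ± 0.14, -0.50 ± 0.14 and -0.30 ± 0.14 (0.0315), the integrin gene ITGB8 0.97 ± 0.23, -0.64 ± 0.23 and -0.58 ± 0.23 (0.0411), and TENM2 0.86 ± 0.16, -0.47 ± 0.16 and 0.03 ± 0.16 (0.0410). TNF had -1.04 ± 0.20, 0.11 ± 0.20 and 0.57 ± 0.20 (0.0315), CYB561D1 -0.21 ± 0.12, 0.83 ± 0.12 and 0.24 ± 0.12 (0.0315) and DANCR -0.20 ± 0.10, 0.57 ± 0.10 and 0.12 ± 0.10 (0.0435). TNF was lost with an offset of 64 (0.143) and TENM2 with an offset of 1 (0.0606). SLC16A7 (0.997) and BSG (0.780) did not pass. Between HS578T and SUM149PT 27 genes differed (20 higher, 7 lower in HS578T), and between HS578T and SUM159PT 5 (4 and 1). Between SUM149PT and SUM159PT limma called 0. There 647 genes (4.58%) had an unadjusted p under 0.05, no more than the share of 0.05 that chance alone gives. Hypoxia-responsive genes were higher in HS578T by a median of 0.53 than in SUM149PT, with 7 of 23 passing and 14 adjusted over the list alone (camera adjusted p = 1.82e-17, and 1.16e-06 with an estimated correlation). Against SUM159PT the median was 0.35, with 3 passing and 12 adjusted over the list alone (1.59e-20, and 3.71e-07 with an estimated correlation). YAP and TAZ targets were 0.28 higher in HS578T than in SUM149PT (1.15e-05, and 0.00774 with an estimated correlation) and cholesterol genes 0.14 higher than in SUM159PT (4.41e-04, and 0.0384 with an estimated correlation). The other 13 list differences were lost in the other version of the test, among them glycolysis (0.10 and 0.12; adjusted p = 0.478 and adjusted p = 0.297 with an estimated correlation). The glycolysis difference from SUM149PT was also lost without HS578T DMSO array 3 (0.07, adjusted p = 0.136), SUM149PT DMSO array 2 (0.00199, 0.239) or SUM149PT AZD3965 array 1 (-0.00565, 0.394). That from SUM159PT was lost without SUM159PT DMSO array 2 (0.04, 0.0778) or AZD3965 array 1 (0.10, 0.119).

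For the test of differing effects 1412 genes (9.99%) had an unadjusted p under 0.05, where chance alone gives a share of 0.05. With array weights 148 genes passed, including all 17, with an offset of 1 the count was 26, with the mean of probe sets 10 and with only the 18 arrays of the inhibitor experiment 9. The count of 17 was 3 without HS578T DMSO array 1, 7 without HS578T DMSO array 3, 8, 7 and 9 without HS578T AZD3965 arrays 1, 2 and 3, 4 and 6 without SUM149PT DMSO arrays 1 and 2, 46, 4 and 5 without SUM149PT AZD3965 arrays 1, 2 and 3, and 9 without SUM159PT DMSO arrays 1 or 2. PDK1 passed in all 18 of these fits but not with the mean of its probe sets (0.423), and HK2 passed in 9, CYB561D1 in 8, TENM2 in 7, TNF in 6, ITGB8 in 5 and DANCR in 4, with adjusted p up to 0.169.

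In SUM149PT, the line with both perturbations, the shRNA effect was set against the AZD3965 effect. AGR2 was 3.66 ± 0.23 (SE, n = 3 per group) higher on the log2 scale in the shRNA contrast than in the AZD3965 contrast, where it measured 0.05. The genes CH25H and KLF4 differed by 2.57 ± 0.35 and 2.54 ± 0.15 and IGFBP7 by -2.94 ± 0.23, each with an adjusted p of 5.19e-05 or less. The IGFBP7 difference, with 1 group under the offset, was -4.10 with an offset of 1 and -1.75 with an offset of 64. NKAPP1 differed by 2.48 ± 0.55, TP53I11 by -2.26 ± 0.57, the T-box gene TBX2 by -2.00 ± 0.50 and ARID5A by -1.82 ± 0.53 (0.00549 to 0.0335). In those 4 genes the AZD3965 effects, -1.35, 1.40, 1.2 and 0.67, did not pass (0.143 to 0.383). NKAPP1, TP53I11 and TBX2 had group means under 25 units, so the offset weighs on their sizes, and TBX2 was lost with an offset of 1 (-0.54, 0.550). ARID5A was lost in 7 of 12 fits that left out an array, with adjusted p up to 0.109 without DMSO array 1. SLC16A7 differed by 1.17 ± 0.34 (0.0326), passing in 5 of 12 such fits with up to 0.106 without DMSO array 1, and BSG by -0.16 ± 0.10 (0.352). In all, 1346 genes differed, 648 higher and 698 lower with shRNA. The share that were higher was 48.1%, and 34.4% with each array centred on its median. The count was 854 with the mean of probe sets, 795 with only the arrays of the comparison and 874 without SUM149PT DMSO array 1.

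The ATF4 list was 0.61 higher in the shRNA contrast, with 18 of 28 genes higher and 23 adjusted over the list alone (camera adjusted p = 3.63e-20, and 1.14e-05 with an estimated correlation), among them SLC3A2 (1.61 ± 0.11) and SLC7A11 (1.63 ± 0.14). Mitotic genes were lower by a median of -0.39, with 15 of 28 lower and 22 adjusted over the list alone (7.78e-14, and 1.14e-05 with an estimated correlation), among them TPX2 (-0.79 ± 0.13). Hypoxia-responsive genes had a median of 0.39 with 10 of 23 higher (2.19e-08, and 6.51e-05 with an estimated correlation), among them VEGFA (1.28 ± 0.16). The unfolded protein response (0.30, 6.97e-06), glutamine and aspartate (0.19, 2.91e-04) and MondoA (0.50, 0.00142) lists also held with an estimated correlation (0.00823, 0.00823 and 0.00984). Oxidative phosphorylation (-0.17), serine (0.40), cholesterol (-0.15), DNA replication (-0.20) and epithelial genes (0.21) passed with the preset value but not with adjusted p = 0.784, 0.111, 0.111, 0.0638 and 0.185 with an estimated correlation. Without scramble shRNA array 3 the ATF4, mitotic and hypoxia lists had adjusted p of 1.19e-21, 4.03e-16 and 1.46e-08, and oxidative phosphorylation 0.789. The log2 fold changes of both perturbations had a Pearson r of 0.014 and a Spearman rho of 0.0069 across 14141 genes, which are not independent replicates. Of the 2101 genes called with shRNA, 1019 (48.5%) had the same sign with AZD3965, and 0 were called by limma in both, where 0.594 would be shared by independent lists. The contrasts had no control arrays in common. The actin control ratio was higher on every shRNA array than on any inhibitor array, and whether this affected the comparison was not tested. With 4 genes called for AZD3965 in this line, noise in that contrast also draws r toward 0. An r this low therefore cannot tell unlike effects from a weak AZD3965 effect.

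Under DMSO the 3 lines differed widely, and 10892 of 14141 genes passed the limma F test. HS578T had the highest signals of collagen and matrix genes, COL1A2 at 28585 ± 2812 units, COL3A1 at 29797 ± 1468, the proteoglycan LUM at 11923 ± 1839 and the sulfatase SULF1 at 20520 ± 1320 (SD, n = 3), against at most 127 units in the other lines. SUM149PT was highest in the adhesion gene CDH1 (8772 ± 596), the tight junction gene CLDN7 (7042 ± 821), the iron-binding LCN2 (15040 ± 1086) and the metalloreductase STEAP4 (11257 ± 726), against at most 38.2 units elsewhere. SUM159PT was highest in ADGRF5 (5445 ± 108), INSC (2680 ± 88.5), MAGEC2, a cancer-testis antigen gene (7547 ± 322), and the neuronal pentraxin gene NPTX2 (9485 ± 413), against at most 53.3 units. In the order HS578T, SUM149PT, SUM159PT, the epithelial gene EPCAM measured 12.5, 14967 and 54.6 units, the basal keratin KRT5 31.6, 2029 and 25.9, the mesenchymal filament gene VIM 23624, 9516 and 23441, and the mesenchymal regulator ZEB1 4895, 86.1 and 3763. SLC16A7 measured 650 ± 31.0, 273 ± 118 and 1358 ± 234 units (adjusted p = 3.42e-08) and BSG 2747 ± 112, 2328 ± 25.5 and 1989 ± 161 (1.58e-05).

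Between pairs of lines 9079 genes differed for HS578T against SUM149PT (4298 higher), 8207 for HS578T against SUM159PT (3865 higher) and 8397 for SUM149PT against SUM159PT (4248 higher). Mesenchymal markers were higher in HS578T than in SUM149PT by a median of 3.48, with 23 of 25 passing as higher (camera adjusted p = 1.49e-05 with an estimated correlation), while epithelial markers (-4.48, 20 of 21 lower) and NF-kappaB genes (-3.29, 20 of 23 lower) were lower, each at adjusted p = 0.0047 with an estimated correlation. Against SUM159PT, HS578T was higher in mesenchymal markers (1.09, 19 of 25) and cholesterol genes (1.16, 17 of 19) and lower in nucleolar genes (-0.93, 16 of 19), at adjusted p = 3.39e-04, 0.00635 and 0.0427 with an estimated correlation. SUM149PT was higher than SUM159PT in epithelial (4.16, 21 of 21), NF-kappaB (3.53, 20 of 23) and basal genes (2.57, 9 of 12) and lower in mesenchymal markers (-1.53, 15 of 25), at adjusted p between 0.00254 and 0.01 with an estimated correlation. Of 8, 12 and 4 lists called in the 3 pairs, 3, 3 and 4 held with an estimated correlation.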

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

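The tests weighed below had their expected outcomes written before they were run, while leaving out scramble shRNA array 3 and drawing random matched lists were chosen after the data were seen. The AZD3965 effect differed between cell lines for 17 genes by a test of the difference itself. In HS578T minus the mean of the other lines, the log2 difference was 1.01 for PDK1, 1.01 for HK2, 1.58 for ITGB8, 1.07 for TENM2, -1.39 for TNF, -0.75 for CYB561D1 and -0.54 for DANCR. Gene lists whose effects differed numbered 6 between HS578T and SUM149PT, 10 between HS578T and SUM159PT and 1 between SUM149PT and SUM159PT. With an estimated correlation 2, 2 and 0 of these held. Outside the genes analysed, 230 of 5649 probe sets without a single gene symbol differed between MCT1 and scramble shRNA, 123 of them higher. That was 4.07% of those probe sets, against 14.9% of genes. The shares are not alike, since each gene stood for its probe set of highest mean. The probe sets without a single symbol were counted singly and tested separately.

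The 2101 genes called with MCT1 shRNA were weighed against the high 3' to 5' control ratios of scramble shRNA array 3. Degraded RNA on that array was expected to leave under 50 percent of the calls without it, or to end the calls of the ATF4 and mitotic lists. Without it 67.1 percent stayed called in the same direction and both lists stayed called (adjusted p = 1.64e-27 and 2.69e-23 by camera in limma). Leaving it out kept 1409 calls, the fewest of the 6 arrays, against 1462 to 1479 without a single MCT1 shRNA array and 1637 and 1782 without the other scramble arrays. Most calls did not rest on the array, although oxidative phosphorylation changed sign without it. Whether the changes follow from loss of MCT1 or from other effects of this shRNA could not be separated with 1 shRNA sequence. The 67.1 percent bears only on scramble shRNA array 3. Scramble shRNA array 1, with the next highest actin ratio at 2.14, stayed in that fit.

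Hypoxia-responsive genes higher with AZD3965 in HS578T were weighed against scaling and against a single array. Their median lay at percentile 100 of random lists matched on mean expression, and the call held under quantile normalization. The highest adjusted p without any 1 of the 6 arrays was 4.95e-26. Neither explanation fitted, and a response of the cells to the inhibitor remains possible, within what 3 arrays per group of unstated independence can show.

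Oxidative phosphorylation genes higher with AZD3965 in SUM149PT and SUM159PT were weighed against scaling that depends on intensity. Their medians lay at percentiles 88.7 and 84.6 of random matched lists, and both calls were lost under quantile normalization (adjusted p = 0.564 and 0.240 by camera in limma). Both outcomes are what such scaling would give, so these shifts are likely not specific to the pathway.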

How the results depend on the processing

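Alternatives for the random matched lists, scramble shRNA array 3, and median centring, the 60th percentile filter, offset 64 and array weights for gene lists were chosen after the data were seen. Of the values of named genes under all alternatives, 4881 kept direction and side of the threshold, including values called in neither fit. With the direction kept, 357 lost their call and 94 gained one. A further 23 changed sign with no call in either fit, and 1 changed sign with a call (reversed). Of the gene list values 1187 kept both, 145 lost their call, 55 gained one and 2 reversed. List values called in neither fit were left out, so the tallies for genes and lists are not alike. For the counts that moved beyond 1.5-fold the cause was not tested. Under quantile normalization SUM159PT had 1 gene, and lists called numbered 1 in SUM149PT, 0 in SUM159PT and 3 for the average. Under median centring SUM159PT had 1 gene and the average 7, with 2 lists in SUM149PT and 7 in SUM159PT. With an offset of 1, SUM159PT had 9 genes, the average 7 and the difference between lines 26, and with the filter at the 60th percentile SUM159PT had 2. With the mean of probe sets HS578T had 26 genes, SUM149PT 2, the difference between lines 10 and the shRNA against AZD3965 difference 854, with 1 list in SUM149PT and 2 in SUM159PT. Without the trend the average had 0 genes. Array weights gave 388 genes in HS578T, 188 in SUM149PT, 5 in SUM159PT, 147 for the average and 148 for the difference between lines, with 2 lists in SUM159PT. With only the arrays of the comparison the counts were 864 for shRNA, 28 in HS578T, 0 in SUM149PT, 9 for the average, 9 for the difference between lines and 795 for shRNA against AZD3965. The 12 correlations between arrays of the same number ran from -0.131 to 0.0834, none over 0.1, so the numbers were not taken as pairs. AZD3965 arrays correlated best with the DMSO array of their own number for 3 of 3 in SUM149PT, 0 of 3 in HS578T and 1 of 3 in SUM159PT, and MCT1 shRNA arrays with scramble arrays for 0 of 3. With a replicate block HS578T had 8, the average 1 and the difference between lines 1. With an estimated correlation 0 lists were called in SUM149PT, 0 in SUM159PT and 1 for the average. Leaving out 1 array at a time, counts ran from 1547 to 2303 for shRNA, 15 to 32 in HS578T, 2 to 648 in SUM149PT, 0 to 4 in SUM159PT, 0 to 66 for the average, 3 to 46 for the difference between lines, 874 to 1774 for shRNA against AZD3965 and 10578 to 10722 between lines. Lists called ran from 11 to 13 for shRNA, 8 to 12 in HS578T, 1 to 4 in SUM149PT, 1 to 7 in SUM159PT and 6 to 8 for the average. Values that reversed were BUB1 with shRNA (0.12, mean of probe sets), oxidative phosphorylation with shRNA (0.10, without scramble shRNA array 3) and reference genes in SUM149PT (-0.035, quantile normalization), and the cause was not tested. List medians also changed sign, with the direction of the test kept, for glycolysis in HS578T minus SUM149PT (-0.00565, not called, without SUM149PT AZD3965 array 1) and glutamine and aspartate metabolism with shRNA (-0.04, still called, median centring). Alternatives for the level of the targeted gene were not run. Signal over background limits dim genes, whose fold changes shrink with the offset.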

Other observations

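The shRNA in SUM149PT and AZD3965 in HS578T shared 15 called genes. Both raised NDRG1 (log2 fold change 1.41 with shRNA and 0.50 with AZD3965), P4HA1 (0.62 and 0.49), BNIP3 (0.39 and 0.65), TMEM45A (1.30 and 0.36), the arginine synthesis gene ASS1 (1.23 and 0.40), the hyaluronan synthase gene HAS2 (0.73 and 0.72), the small GTPase gene RHOB (0.58 and 0.62), TENM2 (0.50 and 0.86), SLC2A1 (0.25 and 0.44), ATP1B1 (0.24 and 0.39) and PGM1 (0.18 and 0.28). These 11 genes compare with 2.17 for independent lists, but the contrasts were not alike over all genes. Both contrasts also used the same estimate of each gene's spread, so genes of low spread pass more easily in both. References for independent lists may therefore be too low. The log2 fold changes of the contrasts correlated at r = -0.028 over all genes. Of the 2101 shRNA calls, 1095 (52.1%) had the same sign in HS578T, and 22 of the 43 HS578T calls (51.2%) had the same sign with shRNA. The immediate early gene EGR1 rose with shRNA and fell with AZD3965 (0.75 and -0.68), and EFEMP1 (-0.61 and 0.27), NMU (-0.68 and 0.80) and PNLIPRP3 (-0.65 and 0.90) did the reverse, 1 and 3 genes against 0.939 and 2.29. Genes lower in both numbered 0 by limma, against 0.993. Hypoxia-responsive and unfolded protein response lists were higher and mitotic genes lower in both, while cholesterol genes were lower with shRNA and higher with AZD3965. The contrasts had no arrays in common, and differences between them were not tested. Across 14141 genes the AZD3965 effects correlated at r = -0.10 between HS578T and SUM149PT, 0.066 between HS578T and SUM159PT and 0.17 between SUM149PT and SUM159PT, the genes not being independent replicates.

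Other splits of the same arrays were counted, with the expected outcome written before. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. As many genes as the real split were called in 1 of 10 splits for shRNA (2101, highest other 1), 1 of 10 in HS578T (43, highest other 6), 1 of 10 in SUM149PT (4, highest other 2) and 10 of 10 in SUM159PT (0, highest other 11). With a real count of 0 the SUM159PT comparison is fixed in advance and tests nothing. For the average it was 2 of 100 splits (4, highest other 4), for the difference between lines 1 of 100 (17, highest other 10), for shRNA against AZD3965 1 of 100 (1346, highest other 1305) and between lines 1 of 100 (10892, highest other 6499). For shRNA against AZD3965 the splits shuffled each experiment separately, so some kept the real shRNA grouping. Other splits of 3 against 3 mix treated and control arrays in a group, so a real difference adds to their spread and lowers their counts. For the difference between lines the treatment labels were shuffled within each line. Those splits stand for no effect in any line, not for equal effects in all lines.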
